A study of Drosophila melanogaster with 2 samples.

How the data were processed

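Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of mixed sex, collected from 0 to 24 h of development. The flies carried ERR, the fly oestrogen-related receptor, fused at its C-terminus to green fluorescent protein, and an antibody against that tag was used for the precipitation, per the labels. Chromatin was sonicated, with a stated size range of 200 to 800 bp. The labels describe 2 biological replicates, numbered 2 and 3, which form 1 group. A possible control experiment is named in the labels and was not used here, so no comparison with untagged or input chromatin could be made.

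Region lists in the narrowPeak layout were used as the authors deposited them, for the genome builds dm6 and dm3. There were 8 lists. For each build they comprised 1 relaxed list of 30000 regions per replicate, 1 relaxed list of 30000 regions from the pooled replicates, and 1 optimal set chosen by the irreproducible discovery rate (IDR), a measure of how well region ranks hold between replicates. The parentage of each list comes from the notes deposited with the files. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of each region is the peak caller's own, as the authors deposited it, and is not scaled between lists. The deposited −log10 q-value column is the caller's value for each region, and the p-value column is marked as not given. In the dm6 optimal set every peak has the same −log10 q of 3.89, so peaks were ranked by signal alone. The dm6 optimal set was identical to the 2892 highest-signal regions of the pooled list, so pooled signal decides membership.

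Depth is unknown, because the lists give no read counts, and no interval that needs a read count is given. Intervals on shares are 95% Wilson intervals over peaks or genes and cover counting error only. P-values were computed across peaks or genes, which are not biological replicates, so they describe these peak sets and not the spread between embryos. Agreement between replicates was therefore reported separately, and the location, motif, gene list and gene family comparisons were also made in each replicate alone.

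Coordinates are dm6 and 1-based. Gene models were those of Ensembl release 115 (BDGP6.54), with sequence from the NCBI release 6 genome, whose arm lengths fit the dm6 coordinates. The dm3 sequence was not used here, so dm3 lists gave counts, signals and replicate comparisons only. A promoter was defined as the 500 bp on either side of any annotated transcript start. Summits elsewhere were assigned to 5' UTR, coding sequence, 3' UTR, intron, other exon or intergenic sequence, in that order. Locations were compared with 100 draws of random positions on the same arms. Motifs were searched on both strands in windows of 201 bp centred on summits and compared by Fisher's exact test, two-sided, with windows centred 1 kb up- and downstream. Benjamini-Hochberg adjustment was applied over the 15 other motifs and over the 16 gene lists.

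Replicate regions were compared by overlap of at least 1 bp between the 2892 highest-signal regions of each list, against 100 shuffles within chromosome arms. Spearman's rho was computed over regions whose summits paired within 100 bp. The tests, gene lists, motifs and alternatives were fixed before the data were examined, except those named below as added. The genes named are ERR, those with a start nearest the 20 highest-signal optimal peaks, those nearest the 10 highest-signal peaks with the ERR motif TNAAGGTCA, and up to 4 members of each list with the highest promoter peaks. Other genes named were chosen after their values were seen. Listed symbols that matched no single gene model, such as Tkt, Pcb, Tor, Mex1, nos and sop, were left out of their lists.

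The alternatives were a stricter set (the higher-signal 50% of optimal peaks), the regions of each replicate alone, 1000 or 5000 top regions, reciprocal overlap of 50%, other summit distances, promoters of 200 or 1000 bp, motif variants, windows of 101 or 501 bp, random windows matched within 5 percentage points of GC content and by distance class, 20 scrambled motifs, a background of genes with any pooled region, peaks anywhere in the gene, and build dm3. A second baseline for replicate overlap, the ranks of named peaks in each replicate, the comparisons of the 15 other motifs by signal and at promoters, the grouping of the DREF and M1BP motifs, and the gene families and tests of explanations of the closing section were added after seeing the data. So were the values of these motif and family comparisons in each replicate alone.

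The scripts were tested on simulated data. All 200 planted motifs were found among 2892 windows, and 1892 of 1892 peaks shifted by 50 bp overlapped their sources. Of the peaks shifted by 50 kb, 57 overlapped another peak by chance. At an unadjusted threshold of 0.05, the gene list test called 199 of 200 enriched lists of 20 genes and 1 of 200 unenriched ones. The enriched lists were planted with a share far above the background. That result does not give the power for smaller lists, weaker enrichment or adjusted p-values. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9.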

Results

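ERR is a nuclear receptor known to activate glycolytic genes in the fly embryo. Its tagged form was mapped by ChIP-seq in 2 biological replicates of whole embryos aged 0 to 24 h, which form a single group. The optimal set held 2892 peaks on the dm6 build, with a median width of 404 bp and a median signal of 97.8 in the peak caller's units. Signals ran from 69.2 to 3946. On the dm3 build the same libraries gave 2930 peaks with a median signal of 97.2. The depth of each library is unknown.

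The highest peaks lay at genes of sugar metabolism. The strongest of all, with a signal of 3946, covered the promoter of Pglym78 (FBgn0014869; 3R, 29147908 to 29148620), which encodes phosphoglycerate mutase, and its summit fell in the 5' UTR 41 bp from a start. Pgk (FBgn0250906; 2L, 2748218 to 2748874), encoding phosphoglycerate kinase, came next with a signal of 2675 and a 5' UTR summit. Ald1 (FBgn0000064; 3R, 26261192 to 26261847), encoding aldolase, had a signal of 2559 at an intergenic summit 7 bp from its start. The glycogen phosphorylase gene Glyp (FBgn0004507; 2L, 2130060 to 2131035) and the phosphoglucomutase gene Pgm1 (FBgn0003076; 3L, 16128360 to 16129149) followed among metabolic genes, with signals of 1706 and 1630. The promoters of Pglym78, Pgk and Ald1 ranked 1, 2 and 3 in both replicates.

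Other glycolytic genes among the 20 strongest peaks were Tpi with a signal of 1096, Gapdh2 with 1052 and Pfk with 1046. The same 20 peaks also lay nearest to genes of other functions. The peak nearest cbt, which encodes a zinc-finger transcription factor, had a signal of 1667 and lay 1415 bp from its start, inside an intron of ush. Ugalt, encoding a UDP-galactose transporter, had a promoter signal of 1239, and CG14100 had 1125. Signals between 776 and 1032 were found nearest CG11050, px, Lk6, CG12824, ph-p, PNPase, CG1888, Chro and larp. The peak nearest CG12824 (2R, 7791207 to 7792047), 1048 bp from its start, also neighboured the promoter peak of the glycolytic gene Gapdh1 (2R, 7792748 to 7793302; signal 283). Which of these genes it serves was not tested. All of these 20 peaks ranked within the 25 highest regions of each replicate.

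ERR itself (FBgn0035849; 3L, 8183361 to 8186671) carried a peak at its own promoter, at 3L, 8185724 to 8186127. The summit lay in an intron 256 bp from a start, with a signal of 202.6. It ranked 305 in the optimal set, 297 in replicate 2 and 290 in replicate 3, and its summit window held no ERR motif. The labels describe the flies as transgenic, and the copy number of ERR DNA in them was not examined.

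The replicates shared most of their highest regions, and less of the order within them. Of the 2892 highest regions of replicate 2, 2038 (70.5%, 95% Wilson interval 68.8 to 72.1) overlapped one of the 2892 highest of replicate 3. The reverse share was 71.2%. Shuffled positions gave a mean of 1.60% and at most 2.25%. Random regions from replicate 2's own list, a baseline chosen after seeing the data, gave a mean of 11.8% and at most 13.1%. Across 11280 paired regions, which are not independent replicates, Spearman's rho of signal was 0.649, and the median ratio of replicate 2 to replicate 3 was 1.21 (quartiles 0.913 and 1.58). Over pairs in the highest 2892 of either replicate rho was 0.544.

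**Figure D1:**
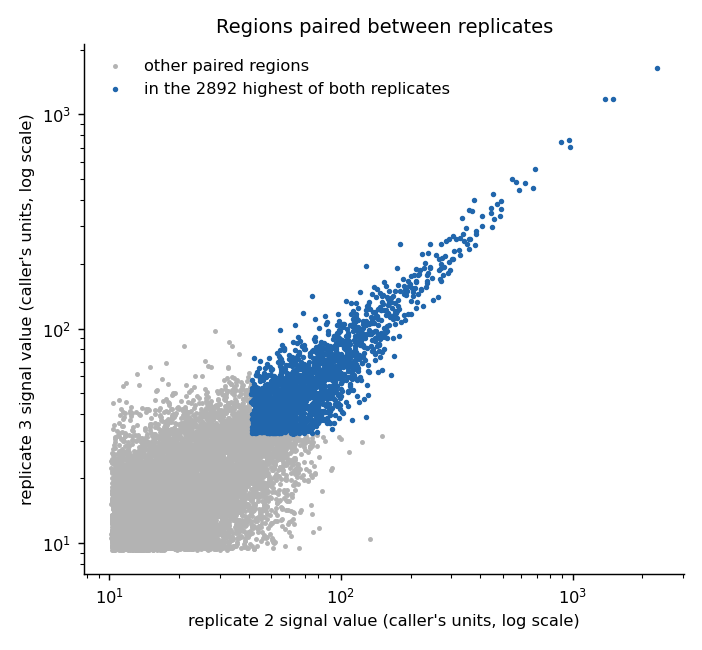
Signal of 11280 regions paired by summit between replicate 2 (x axis) and replicate 3 (y axis), both in the caller's units on log scales, 1 point per pair. Blue points are among the 2892 highest of both replicates, and the point at the upper right is the Pglym78 promoter, with 2317 and 1645.

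Each replicate alone carried most of the optimal peaks. Of the 2892 peaks, 86.9% (85.7 to 88.1) overlapped a top region of replicate 2, 81.0% (79.5 to 82.4) one of replicate 3, and 70.0% (68.3 to 71.6) top regions of both. Membership of the optimal set follows the pooled signal of these same replicates, so part of this overlap is built in. A peak can also be included with a low rank in 1 replicate. The promoter peak of the nuclear receptor gene Eip75B, at 3L, 17999766 to 17999953, ranked 330 in replicate 3 and 4387 in replicate 2.

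With promoters of 500 bp, glycolysis and trehalose and glycogen metabolism had the highest shares of genes with promoter peaks among the 16 lists. With promoters of 1000 bp or summits anywhere in the gene, the pentose phosphate pathway had the highest share (7 of 7 genes). Among 13 glycolysis genes, 12 had an optimal summit within 500 bp of a start, and Hex-C, a hexokinase gene chosen for mention after its value was seen, was the exception. Their median signal was 853, with Pglym78, Pgk, Ald1 and Tpi highest. Of 10 trehalose and glycogen genes, 9 had a promoter peak, with Glyp, Pgm1, the glycogen synthase gene Glys (signal 712) and the UDP-glucose pyrophosphorylase gene UGP (419) highest and Tps1, named after its value was seen, without one. The share over all 13945 protein-coding genes was 15.1%, or 2105 genes. Fisher's exact test gave an odds ratio of 67.9 (adjusted p = 1.2e-08) for glycolysis and 50.8 (adjusted p = 1.8e-06) for trehalose and glycogen. With promoters of 200 bp the ratios fell to 17.6 (9 of 13 genes) and 7.79 (5 of 10), and against genes with any pooled region near a start they were 32.7 and 24.5. In the higher-signal 50% of peaks glycolysis stood at 136, and all of these values passed. Of the 1710 peaks near a protein-coding start, 562 (32.9%) lay near starts of more than 1 gene, so a peak does not always identify its gene.

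**Figure D2:**
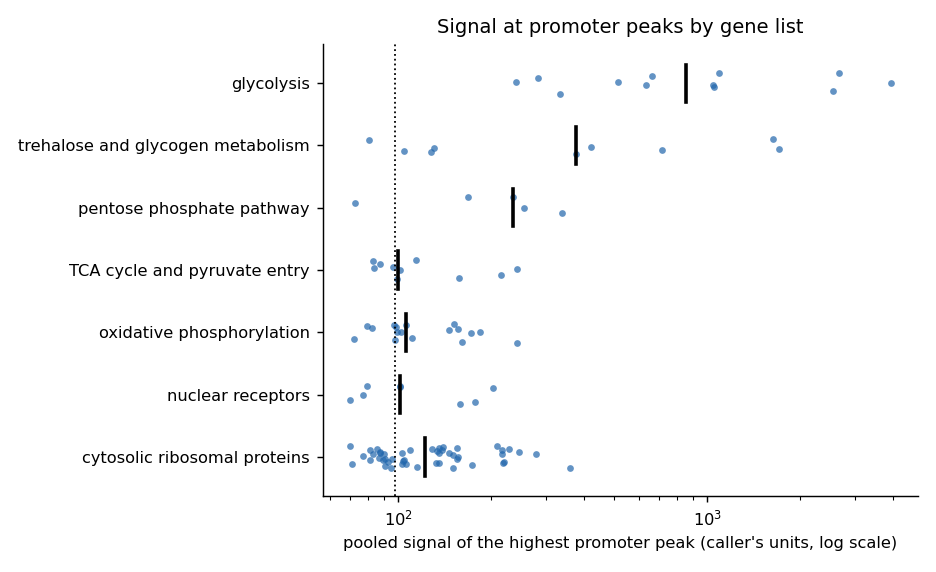
Pooled signal, in the caller's units on a log scale, of the highest promoter peak of each gene with one, for 7 gene lists. Points are genes, vertical bars are medians and the dotted line is the median of all optimal peaks (97.8); the glycolysis median is 853 and that of the ribosomal protein genes 122.

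Neighbouring branches of sugar metabolism also held promoter peaks, with lower signals. In the pentose phosphate pathway, 5 of 7 genes had one, led by CG8036 (signal 339), Taldo (256), Rpi (236) and Rpe (168). In the TCA cycle and pyruvate entry, 10 of 22 genes had one, led by Fum1 (signal 242), Mdh1 (214), mAcon1 (158) and muc (114). Both lists passed Fisher's exact test, with odds ratios of 14.1 (adjusted p = 0.00401) and 4.70 (adjusted p = 0.00271). Against genes with any pooled region near a start, neither passed, with odds ratios of 6.79 and 2.47. For the pentose phosphate list the ratio was 7.19 in replicate 2 alone, and with promoters of 200 bp it was 5.83 and did not pass.

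Genes of oxidative phosphorylation and of lipid metabolism did not pass the test. A promoter peak was found at 17 of 86 oxidative phosphorylation genes, led by ND-ASHI (signal 242), ND-20 (184), ND-MWFE (172) and ND-51 (161), and ND-ASHI shares its peak with Fum1. The odds ratio was 1.39 (adjusted p = 0.340, Fisher's exact test). In the higher-signal 50% of peaks it was 2.02 (adjusted p = 0.0625, Fisher's exact test), and against genes with any pooled region near a start 1.05. The list was built from symbol patterns, so it also holds like-named relatives such as ATPsynbetaL, without a peak, and COX7AL2, with one. Fatty acid oxidation had 5 of 14 genes, led by whd (signal 96.6), Mtpbeta (84.3), Etfb (82.6) and Etf-QO (80.4), with an odds ratio of 3.13 that did not pass (adjusted p = 0.0905, Fisher's exact test). It passed with promoters of 200 bp (4.32, adjusted p = 0.0424) or 1000 bp (3.54, adjusted p = 0.0479) and with summits anywhere in the gene (3.42, adjusted p = 0.0487), by Fisher's exact test. It also passed in replicate 3 alone, with a ratio of 6.06, but was 0.897 in replicate 2 alone and 0 in the higher-signal 50% of peaks. Lipid synthesis and storage had 3 of 13 genes, Lpin (signal 158), AcCoAS (116) and SREBP (93.5), with an odds ratio of 1.69 (adjusted p = 0.574, Fisher's exact test). Counting summits anywhere in the gene raised that ratio to 7.30, past the threshold. It was 3.37 in replicate 2 alone (5 of 13 genes, adjusted p = 0.0806, Fisher's exact test), 1.81 in replicate 3 alone and 0.813 against genes with any pooled region near a start.

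Ribosomal protein genes often held promoter peaks, at moderate signal. Promoter peaks lay at 48 of 93 cytosolic ribosomal protein genes (51.6%, 41.6 to 61.5), with RpL7 (signal 359), RpL23A (280), RpS28a (246) and RpL14 (228) highest and a median of 122. The odds ratio was 6.12 (adjusted p = 2.6e-15, Fisher's exact test). The peaks at RpL7, RpS28a and RpL14 also lay within 500 bp of starts of Ripalpha, Axn and Nelf-E, and that at RpL23A near no other gene. Among nuclear receptor genes, 8 of 21 had a promoter peak, led by ERR (signal 202.6), Eip75B (177), Hr96 (158) and svp (102), with an odds ratio of 3.47 (adjusted p = 0.0197, Fisher's exact test). With promoters of 200 bp that ratio was 1.29 and did not pass. Hypoxia and insulin signalling had 6 of 12 genes, led by Thor (signal 139), InR (94.8), sima (85.2) and foxo (79.1), with an odds ratio of 5.64 (adjusted p = 0.0127, Fisher's exact test). In replicate 3 alone it was 2.02 and in replicate 2 alone 3.85, and neither passed. Neither of these last lists passed in the higher-signal 50% of peaks (odds ratios 3.53 and 1.02) or against genes with any pooled region near a start (3.11 and 3.26).

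None of the 6 lists of tissue marker genes passed the test. Muscle genes had promoter peaks at 3 of 23, namely Msp300 (signal 279), sls (224) and Mef2 (77.8). Neuronal and glial genes had them at 2 of 16, moody (358) and elav (232), and fat body and blood cell genes at 1 of 15, Adh (270.0). No peak lay at the promoters of 12 trachea and epidermis genes or 8 germ line genes, shares whose upper 95% bounds are 24.2% and 32.4%. The midgut list had 4 of 10, with fkh (231), Vha55 (225), Vha100-2 (193) and Vha16-1 (96.9). Of its genes, 4 encode vacuolar ATPase subunits, 3 of them with a peak, so the midgut share rests mostly on that family. Adjusted p was 0.0905 for midgut, 0.817 for fat body and blood cells, 0.340 for trachea and epidermis, 0.758 for germ line, and 1 for muscle and for neurons and glia (Fisher's exact test). The midgut list passed in replicate 3 alone, with an odds ratio of 6.06 against 3.59 in replicate 2 alone.

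**Figure D3:**
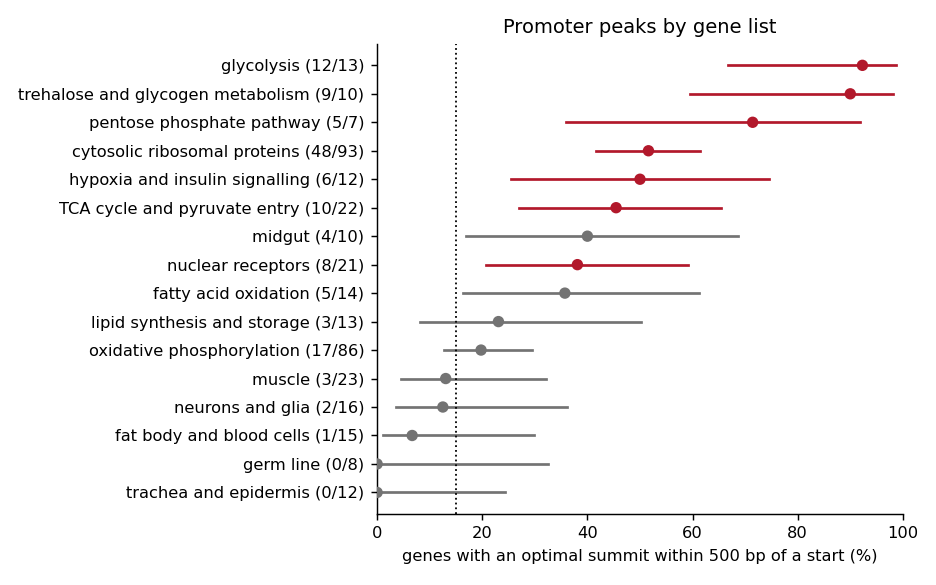
Percent of each list's genes with an optimal summit within 500 bp of a start, for 16 lists, with 95% Wilson intervals over genes. Red marks the 7 lists with adjusted p under 0.05 by Fisher's exact test, and the dotted line is the share over all protein-coding genes, 15.1%.

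Most peaks lay at gene starts. Of 2892 summits, 1794 (62.0%, 60.2 to 63.8) were in promoters, against a mean of 13.6% and at most 15.9% of random positions. Introns held 26.8% against 39.4% at random, intergenic sequence 8.89% against 27.2%, and coding sequence outside promoters 0.242% against 13.8%. In replicate 3 alone the coding share was 0.622%. The median distance to a protein-coding start was 252.5 bp, and 12.0% of summits lay over 5 kb from one. By arm, density ran from 20.5 peaks per Mb on 3L to 23.2 on 2L, and X stood at 0.966 times the large autosome arms (95% interval 0.875 to 1.06). Chromosome 4 held 12 peaks, or 8.90 per Mb (exact Poisson interval 4.60 to 15.5).

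Exact matches to the sequence bound by oestrogen-related receptors were enriched at summits but rare. Sites that depart from the searched sequence were not counted. TNAAGGTCA lay in 47 of 2892 summit windows (1.63%, 1.22 to 2.15) and in 0.519% of windows 1 kb away, an odds ratio of 3.17 (p = 6.4e-07, Fisher's exact test). The ratio was 5.05 in the narrower windows tried and 1.80 in the wider ones. Its strongest carriers were at Pfk (2R, 10110743 to 10111783; 5' UTR summit; signal 1046), Glys (3R, 15146736 to 15147297; 5' UTR; 712), Hex-A (X, 9585457 to 9586010; 5' UTR; 660.3) and Eno (2L, 1727171 to 1727838; 5' UTR; 428). UGP, CG8929, CG9674, the malic enzyme gene Men, GstO2 and CG11357 were nearest the next 6. The core AAGGTCA lay in 3.80% of summit windows and 1.88% of those 1 kb away. It also lay in the summit windows of 14% of the 100 highest peaks.

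The motif was found more often in strong peaks than in weak ones. The 723 highest peaks by signal held TNAAGGTCA in 2.35% of windows and the 723 lowest in 0.415%, an odds ratio of 5.78 (p = 0.00241, Fisher's exact test). In replicate 2 alone the ratio was 1.56 and did not pass, and within the higher-signal 50% of peaks it was 1.00. Promoter peaks carried the motif less often than others, 1.11% against 2.46%, an odds ratio of 0.447 (p = 0.0092, Fisher's exact test).

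Motifs of promoter and chromatin factors were also enriched at summits. The DREF motif TATCGATA lay in 5.53% of summit windows against 0.726% of those 1 kb away (odds ratio 8.01), the M1BP motif GGTCACACT in 2.84% against 0.484% (6.00), and the GAF motif GAGAGAG in 7.30% against 4.36% (1.73). Adjusted p was 1.6e-40, 5.3e-18 and 1.1e-07 by Fisher's exact test. Against matched random windows the odds ratios were 4.65 for DREF, 4.19 for M1BP and 2.96 for GAF. GATA (odds ratio 1.15) and Mef2 (1.25) motifs also passed and the Hnf4 motif was less frequent (0.307), but none of these 3 passed against matched random windows. Mef2 also did not pass in the higher-signal 50% of peaks (1.25, adjusted p = 0.179) or in replicate 2 alone (1.16, adjusted p = 0.290), nor Hnf4 in replicate 3 alone (0.347, adjusted p = 0.0892), by Fisher's exact test. The other 9 motifs did not pass, although the E-box (odds ratio 1.19, against 0.998 with windows 1 kb away) and hypoxia response (1.21) motifs did against matched random windows. DREF and M1BP motifs were found mainly at promoters, with odds ratios of 26.0 and 25.6 against other peaks (adjusted p = 4.0e-27 and 6.3e-14, Fisher's exact test). In replicate 3 alone the M1BP ratio was 9.98. The E-box (0.736) and GATA (0.785) motifs were less frequent at promoters than elsewhere (adjusted p = 0.0103 for each) and the hypoxia response motif more frequent (1.22, adjusted p = 0.0423), by Fisher's exact test. These 3 passed in each replicate alone, and the other 10 motifs did not pass in the comparison of promoters with other peaks. M1BP was less frequent in the 723 highest peaks than in the 723 lowest, 1.24% against 4.43% (odds ratio 0.272, adjusted p = 0.00537, Fisher's exact test). In replicates 2 and 3 alone that ratio was 0.470 and 0.328, and neither passed. For DREF the shares were 3.32% and 5.81%, which did not pass (adjusted p = 0.233, Fisher's exact test), and the 2 groups between them both stood at 6.50%.

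**Figure D4:**
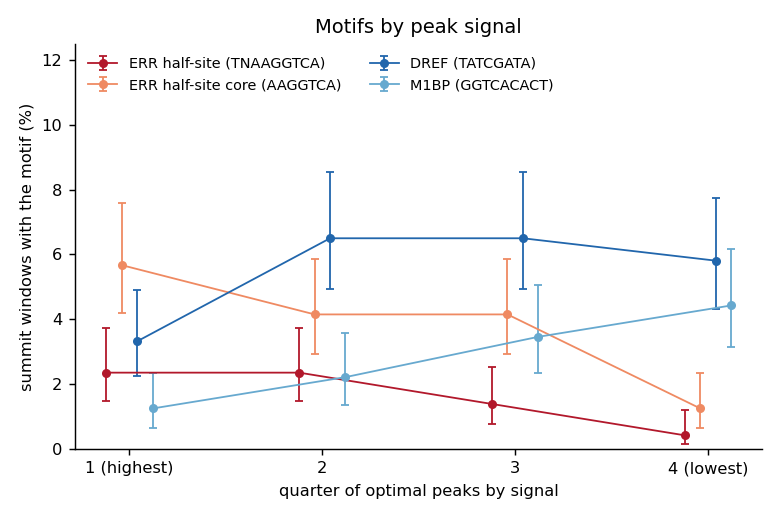
Percent of summit windows with each motif (y axis) in 4 groups of 723 optimal peaks ordered by signal (x axis), with 95% Wilson intervals over peaks. TNAAGGTCA goes from 2.35% in the highest group to 0.415% in the lowest, and GGTCACACT from 1.24% to 4.43%.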

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

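Of 171 alternative values for the comparisons, 129 kept their direction and side of the threshold or stayed within their spread, 13 lost significance, 6 gained it, 15 moved and 8 reversed. Of 154 values for single motifs, families or features, 119 kept both, 12 lost significance, 1 gained it, 1 moved and 21 reversed. Each reversed value had an odds ratio short of the threshold as reported. An odds ratio of exactly 1 was counted as a loss, not a reversal, a rule set after seeing it. The causes were not tested. Replicate overlap was 75.3% with 1000 and 67.9% with 5000 regions, 62.0% with reciprocal overlap and 62.7% with summits within 100 bp. Rank correlation was 0.687 with summits within 50 bp and 0.544 among pairs in the top of either replicate. Recovery in replicates 2 and 3 was 78.9% and 68.1% with reciprocal overlap and 84.0% and 76.2% with summits within 100 bp. Promoter shares were 47.9% at 200 bp and 71.7% at 1000 bp, and 59.5 to 63.8% without each replicate; intron shares were 25.3 to 29.3% without each replicate. The motif's relation to signal had an odds ratio of 1.00 in the higher-signal 50% of peaks, 7.06 with TCAAGGTCA (7 against 1 peaks, no longer past the threshold, p = 0.0696, Fisher's exact test), and 1.56 to 3.06 without each replicate.

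Among lists, the higher-signal 50% of peaks gave odds ratios of 3.53 for nuclear receptors and 1.02 for hypoxia and insulin, which lost significance, and 0 for fatty acid oxidation, 1.07 for muscle and 1.61 for neurons and glia, which reversed. Promoters of 200 bp gave 5.83 for pentose phosphate and 1.29 for nuclear receptors, both lost, and 4.32 for fatty acid oxidation, gained. Promoters of 1000 bp gave 3.54 for fatty acid oxidation, gained, and 1.09 for neurons and glia, reversed. With genes near any pooled region as background, 3 lists passed instead of 7; pentose phosphate was 6.79, TCA 2.47, nuclear receptors 3.11, hypoxia and insulin 3.26, and lipid synthesis reversed to 0.813. Summits anywhere in the gene gave 3.42 for fatty acid oxidation and 7.30 for lipid synthesis, both gained, and 1.52 for neurons and glia, reversed. Without each replicate, hypoxia and insulin ran from 2.02 to 3.85, fatty acid oxidation from 0.897 to 6.06, midgut from 3.59 to 6.06 and muscle from 0.807 to 1.27. For pentose phosphate no odds ratio could be given at 1000 bp or over whole genes, because all 7 genes had a peak.

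Among motifs, calls were lost for Mef2 in the higher-signal 50% of peaks (1.25), in replicate 2 alone (1.16) and against matched random windows (1.26), for Hnf4 in replicate 3 alone (0.347) and against matched random windows (0.399), and for GATA against matched random windows (1.13). M1BP by signal and translation initiation factors lost theirs in each replicate alone, DREF and M1BP together, a pair picked after seeing the data, in replicate 2 alone and mitochondrial ribosomal proteins in replicate 3 alone. Reversals in the higher-signal 50% of peaks were hypoxia response (0.929) and CACGTG (0.931). Against matched random windows they were E-box (1.19, which passed), AP-1 (1.39), Grainyhead (1.29) and ETS (1.27). Without each replicate, E-box ran from 1.01 to 1.07, AP-1 from 0.896 to 1.08 and CRE from 0.832 to 1.13. Replicate values added after seeing the data reversed for motifs at promoters (GAF 0.754 to 1.05, AP-1 0.701 to 0.922, Grainyhead 0.679 to 1.42, ETS 0.994 to 2.05, CACGTG 0.765 to 1.28) and by signal (E-box 0.844 to 1.13, CACGTG 0.773 to 1.67). They also reversed for vacuolar ATPase (0.863 to 1.80), Tim and Tom (0.828 to 1.51) and glutathione S-transferase genes (0.779 to 1.35). Ranks of named peaks, compared after seeing the data, stayed within 1.5 times in 121 of 139 replicate values. Read depth is unknown, so what it limits cannot be stated.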

Other observations

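The comparisons between gene families, the tests of the glycolysis pattern, the count of regions near ERR, the values of single replicates, the grouping of DREF with M1BP and the promoter share and promoter motif share of low-ranked regions were chosen after the data were seen; the other tests of explanations were set before their own results were known. Other groupings of genes by family differed widely. Mitochondrial ribosomal protein genes had a promoter peak at 20 of 73, led by mRpL41 (signal 743), mRpS23 (655), mRpS10 (477) and mRpL23 (305), and translation initiation factors at 13 of 44, led by eIF6 (493). Their odds ratios were 2.13 (adjusted p = 0.0209) and 2.37 (adjusted p = 0.0382) by Fisher's exact test over 11 families. The first was 1.31 in replicate 3 alone and did not pass, and the second passed in neither replicate alone, with 1.80 in replicate 2 and 2.02 in replicate 3. Cuticle protein genes of the Cpr family had peaks at 0 of 70 (upper 95% Wilson bound 5.20%), cytochrome P450 genes at 3 of 85, led by Cyp6u1 (165), and odorant and gustatory receptor genes at 1 of 119, Gr63a (71.5). Adjusted p for these 3 was 8.3e-05, 0.00427 and 1.2e-06 by Fisher's exact test. All 3 passed in each replicate alone; the P450 odds ratio was 0.205 overall and 0.129 in replicate 2 alone, and no receptor gene had a peak in replicate 3 alone.

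No departure was detected for proteasome subunits (10 of 48, led by Rpn6), aminoacyl-tRNA synthetases (8 of 33, led by SerRS) or vacuolar ATPase subunits (7 of 32, led by Vha55; 4 of the 32, 3 of them with a peak, are also in the midgut list). The same held for CCT chaperonins (1 of 8), Tim and Tom import proteins (2 of 15) and glutathione S-transferases (6 of 35), although GstE13 had a signal of 597. Adjusted p lay between 0.265 and 1 by Fisher's exact test. Within 20 kb of the middle of ERR lay 27 regions of the pooled list, against a median of 13 over protein-coding genes, which placed ERR at percentile 92.7. Because the flies were transgenic for ERR and its DNA copy number was not examined, this count cannot be read as binding alone.

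The glycolysis promoters carried far higher signals than other promoters with a peak, with a median 8.39 times that of the other 2093 genes. A permutation test of the difference in mean log2 signal gave p = 2e-05, the smallest that 100000 resamples can give. The other permutation p-values in this paragraph also come from tests of mean log2 signal, not of medians. The median of the ribosomal protein genes with a promoter peak was 0.143 times the glycolysis median (permutation p = 2e-05). A ratio of 0.5 or more was taken to mean high transcription of promoters in general, a bar set after the data were seen. Transcription was not measured in either list, so the ratio does not decide on that explanation. A single replicate was not the source, since the 22 peaks within 500 bp of a glycolysis start had a median rank of 80 in replicate 2 and 59 in replicate 3. A candidate explanation that stays open is a higher density of receptor sites. AAGGTCA lay in the summit windows of 8 of those 22 and 48 of 1772 other promoter peaks, an odds ratio of 20.5 (p = 1.2e-07, Fisher's exact test). In replicates 2 and 3 alone the ratio was 24.9 and 15.2. With only the highest peak of each glycolysis gene counted it lay in 6 of 12, against the same 1772 peaks (35.9, p = 4.7e-07, Fisher's exact test). Neither comparison was matched on signal. Over all optimal peaks the core lay in 5.67% of the 723 highest and 1.24% of the 723 lowest, so these ratios do not separate glycolysis from high signal. The core is absent from 14 of the 22, among them the peaks ranked 1 and 3 at Pglym78 and Ald1, and no relation of the core to signal was detected among glycolysis peaks, with a ratio of medians of 2.63 over the 22, several of which share a gene (690 with and 262 without, exact permutation p = 0.0767), and of 1.01 over the highest peak of each gene (853 and 844, exact permutation p = 0.939); untagged chromatin was not analysed here and no biological explanation was tested by the design.

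Motifs of the promoter factors DREF and M1BP, grouped after both shares were seen to be lower in strong peaks, lay in 4.56% of the 723 highest and 9.27% of the 723 lowest peaks (odds ratio 0.468, and 0.674 and 0.583 in replicates 2 and 3 alone); no p is given because the pair was picked from 15 motifs for this direction, and DREF alone did not pass. A larger share of promoters among weak peaks was not the reason, since 65.3% of the highest and 62.8% of the lowest peaks lay at promoters, and within promoter peaks alone the odds ratio was 0.408. Regions ranked beyond 20000 held the motifs in 1.34%, an odds ratio of 0.133 against the 723 lowest peaks. Promoters were 23.1% of those regions and 62.8% of those peaks, but at promoters alone the shares were 4.43% and 14.8%, an odds ratio of 0.267. No p is given for either ratio, because the share in the 723 lowest peaks guided the choice of the pair. By these shares alone, background like those regions would not raise the share in weak peaks. In the 723 ranks just past the optimal set, 12.4% of promoter regions held either motif, an odds ratio of 0.817 (p = 0.330, Fisher's exact test), so background of the kind found near the threshold cannot be told apart from weak binding. It also remains open whether ERR is recruited with these factors or whether open promoters yield weak signal with any antibody, since no control chromatin was analysed here.

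Ribosomal protein promoters held peaks at 51.6%, against 25.8% of 198 other housekeeping genes (proteasome, tRNA synthetases, mitochondrial ribosome and translation initiation), an odds ratio of 3.07 (p = 2.0e-05, Fisher's exact test). Housekeeping promoters in general therefore do not account for the whole share. Those 198 genes, however, themselves held promoter peaks more often than the rest, with an odds ratio of 2.01 (p = 4.9e-05, Fisher's exact test). Nor did 1 replicate alone carry it, since the odds ratio against other genes was 7.97 in replicate 2 and 5.53 in replicate 3 (p = 1.8e-14 for the latter, Fisher's exact test). Among the highest promoter peak of each ribosomal protein gene, only that at RpL3 held the core AAGGTCA in its summit window. The core lay in the summit windows of 48 of 1772 promoter peaks away from glycolysis genes. Very high transcription of ribosomal protein genes stays open as a technical source and was not tested. Some ribosomal protein promoter peaks, such as that at RpL7, also lay near the start of another gene. The tests count such a peak for both genes.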
